A study of Caenorhabditis elegans with 2 samples.

How the data were processed

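Chromatin immunoprecipitation with sequencing (ChIP-seq) was labelled as performed against FKH-10, a transcription factor of the forkhead (winged helix) family, in whole Caenorhabditis elegans at the third larval stage (L3). Per the labels, the animals were of strain OP337, which carries an integrated transgene encoding FKH-10 with a C-terminal GFP and FLAG tag together with unc-119 as the marker of transformation, and the chromatin was sheared by sonication. Both libraries belonged to 1 group and were labelled as biological replicates 1 and 2. The series held no second condition, so no contrast between groups was made, and peaks or genes rather than animals were the units of each test.

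The authors deposited peak lists in narrowPeak format on builds ce11 and ce10 of the genome. Per the deposited descriptions of the files, a list of candidate regions was called for each replicate and for the pooled replicates against a control alignment. A thresholded list was derived from these by the irreproducible discovery rate (IDR), which keeps regions by how consistently they rank between lists. That list was named optimal, and the rule behind this name was not examined here. The control itself was not analysed here. The signal value of each region was the one the authors' caller gave, with a scaling that was not stated. It served to rank or describe regions within a list and to correlate the replicates across peaks. The authors deposited the −log10 of a q-value for each region, which ran from 3.04 to 3.52 in the thresholded list on ce11 and was used no further. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The number of reads per library is not given either, so the depth behind each signal value is unknown.

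On ce11 the thresholded list held 2005 peaks, and the pooled list and the list of each replicate held 30000 regions each. The thresholded list on ce10 held 2058 peaks. Of the pooled regions on ce11, 99.7% were 364 bp wide, so that the width of a region carried little information. In the thresholded list 57 peaks overlapped the peak before them, and neighbouring summits in such places are not independent. Positions are given on ce11, counted from 1. The ce11 coordinates lay within the chromosomes of the WBcel235 sequence, and genes were taken from Ensembl release 115 on that assembly. No annotation of ce10 was used here, so the ce10 lists entered only counts, overlaps and shares by chromosome.

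A peak was assigned to the protein-coding gene whose annotated 5' end was nearest to its summit, within 1 kb. Of 19973 protein-coding genes on the 6 nuclear chromosomes, 815 (4.08%) received a peak. The share of summits within 1 kb of a gene start, and within 200 bp of 1 of 612 tRNA genes, was compared with 10000 random placements of the summits on their own chromosomes (two-sided permutation test). The forkhead core RTAAAYA (R is A or G, Y is C or T) was searched on either strand within 50 bp of each summit and in a window of the same width centred 500 bp towards higher coordinates, and the windows were compared with an exact two-sided McNemar test. All 8192 7-mers, with strands merged, were tested in the same way with Benjamini-Hochberg adjustment. For 34 gene lists, Fisher's exact test (two-sided) compared the share of members with a peak with that of all other protein-coding genes, adjusted over the lists. Peaks per chromosome were compared with the share of protein-coding genes by exact binomial tests, adjusted over 6 chromosomes. The association of the motif with signal was tested with Spearman's rho over 100000 permutations. The threshold was 0.05 throughout.

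The gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Named were fkh-10 and unc-119, the genes at the 20 strongest thresholded peaks (those with a start within 1 kb, otherwise the nearest), the 4 members with the strongest peak of each list past the threshold, and the 10 7-mers with the smallest p. Any gene named outside this rule is marked where it appears. Alternatives were the 1002 strongest peaks, the 2005 strongest regions of each replicate's own list in place of the thresholded list (leaving out the other replicate), other windows and control windows, the 2005 weakest pooled regions as a comparison, lists matched on upstream length and the ce10 lists. An analysis without 2 blocks of dense summits was added after the data had been seen, and so were the placement of summits within their own class of location, the classes of 7-mers and the definition of a block as 10 or more thresholded summits within 20 kb.

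The scripts were tested on simulated data. All 40 spiked gene lists were recovered and 5 of 300 unspiked lists were called over 19973 genes. All 4 spiked 7-mers were recovered. The 8188 others gave 1 call, leaving out called 7-mers that shared 5 bases in a row with a spiked one. These simulated summits lay at random, without the difference in base composition seen at the real summits. Of 50 random sets of 2005 summits, 1 gave a p under the threshold for random placement. Intervals on shares are 95% Wilson intervals, or exact binomial intervals for gene lists, and cover counting error over peaks or genes only. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.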

Results

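The peaks came from ChIP-seq labelled as against tagged FKH-10 in 2 biological replicates of whole L3 larvae. The thresholded list on ce11 held 2005 peaks covering 737695 bp (0.736% of the 6 nuclear chromosomes). Signal values, as the authors' caller gave them, ran from 28.2 to 182 with a median of 41.8. The depth of the libraries is unknown.

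The replicates were compared at the thresholded peaks, a list already derived from both by IDR. Overlap and correlation thus hold within this chosen set only. Of the 2005 thresholded peaks, 1674 (83.5%) were overlapped by 1 of the 2005 strongest regions of replicate 1 and 1505 (75.1%) by those of replicate 2. Both replicates covered 1221 peaks (60.9%, Wilson 95% interval 58.7% to 63.0%), and neither covered 47. In the full lists of 30000 regions, 3 of the peaks were missing from replicate 1 and 14 from replicate 2, and 1988 were present in both. Across these peaks the signal of replicate 1 and replicate 2 was correlated with a Spearman's rho of 0.366 and a Pearson's r of 0.379 on log2 values. These are correlations across peaks, which are not independent replicates. Neighbouring peaks overlapped by the same replicate region took the same value and were counted separately, as in the dense block on chromosome I described last. The 20 strongest peaks ranked within the first 51 regions of replicate 1 and the first 83 of replicate 2.

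**Figure D1:**
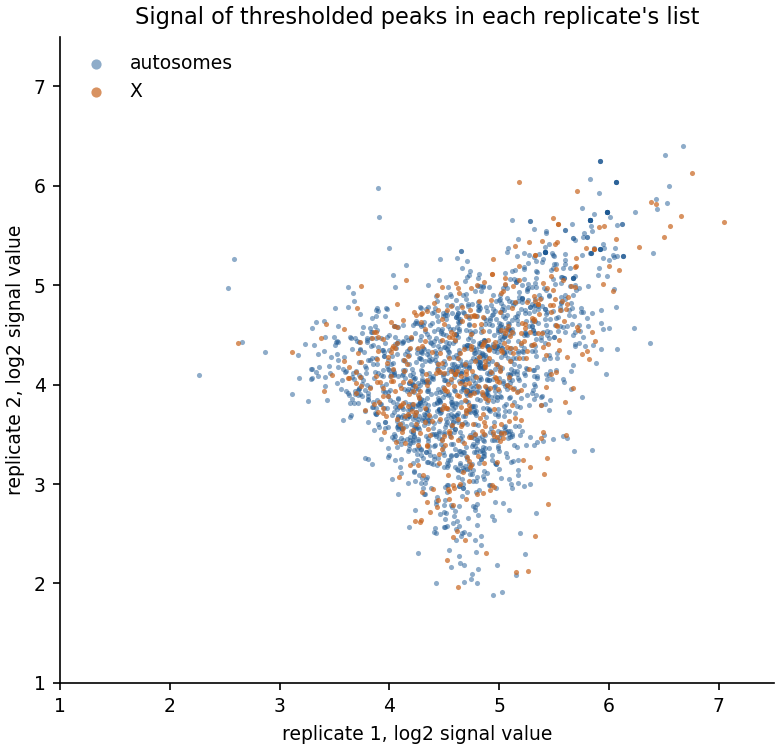
Log2 signal value of each thresholded peak in the list of replicate 1 (x axis) and of replicate 2 (y axis), with 1 point per peak present in both lists. Peaks matched to the same regions in both lists fall on the same point. X-linked peaks are in orange and autosomal peaks in blue. The 1988 peaks form a broad cloud (rho 0.366), and the strongest lie together at the upper right; the scales of the lists were not stated to be the same.

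The strongest peaks lay near rpl-3 and cdc-48.1 and at X-linked sites away from gene starts. The strongest peak (chromosome III, 3867486 to 3867658, signal 182) lay between genes, 273 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. The sequence from 50 bp before to 50 bp after its summit, 3867531 to 3867631, read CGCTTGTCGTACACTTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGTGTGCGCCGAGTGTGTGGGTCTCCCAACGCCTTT. The second (chromosome II, 10563486 to 10563648, signal 173) lay 153 bp from the start of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase of protein quality control. Peaks at rpl-20 and Y17G9B.5 (signal 156), hsp-1 (signal 147), which encodes an Hsp70 chaperone, eef-1A.2 (signal 130), which encodes translation elongation factor 1A, rpl-15 with K11H12.8 (signal 126), rpl-35 (signal 120) and rpl-12 with lin-54 (signal 120) were also among the 20 strongest. Peaks at H41C03.3 with ZK1248.17 (signal 142) and at tasp-1 with K01G5.10 (signal 141) had gene starts within 1 kb as well.

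Of the 20 strongest peaks, 8 lay on X and 9 had no protein-coding gene start within 1 kb, 6 of them on X. The strongest of these (X, 9465677 to 9466040, signal 170) lay between genes, 2514 bp from the start of ZK899.6. The next (X, 2997017 to 2997232, signal 163) lay in an intron of Y41G9A.17. A further one (X, 6296372 to 6296735, signal 144) lay 3388 bp from the start of cest-16, in an intron of mom-1, a gene named after its values were seen. The others on X had the starts of F19H6.5 (1716 bp, signal 135), K02D3.1 (6102 bp, signal 135) and sma-9 (3022 bp, signal 118) nearest, and a peak with signal 130 lay 970 bp from fbxb-58. The autosomal ones lay in introns of unc-42 (chromosome V, signal 128.8), which encodes a homeodomain factor of neurons, and K05C4.3 (chromosome I, signal 122, within a dense block of summits described last), and 1300 bp from ins-13 (chromosome II, signal 119.5). RTAAAYA was present within 50 bp of the summit at 3 of the 20 peaks.

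The tagged gene and the marker of the transgene differed. At fkh-10 (WBGene00001442, chromosome I, 10163475 to 10165132, minus strand) no region lay within 20 kb in any of the 4 lists on ce11, so the lists held no signal at the tagged gene by which the labelled strain could be checked. The gene sat in a stretch of 59142 bp between neighbouring pooled summits, and 5 of 29994 such stretches were at least as long (median 2104 bp). Being long, such stretches held 0.516% of the genome, a share of bases, and the genes in them were not counted. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), needed for the nervous system, a thresholded peak lay in an intron at 10903279 to 10903642. Its signal was 51.1, rank 607 of the thresholded peaks, and the matching regions ranked 392 in replicate 1 and 1543 in replicate 2. This peak was not alone at the gene in the unthresholded lists. There 7 pooled regions lay within 1 kb of unc-119, with 6 and 8 in the lists of replicates 1 and 2. Within 20 kb lay 18 pooled regions. These counts were not compared with those around other genes, and no cause of the regions at unc-119 was tested.

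The peaks were found between genes and near gene starts, and were scarce in coding exons. Of the 2005 summits, 1312 (65.4%, Wilson interval 63.3% to 67.5%) lay between protein-coding genes, against 37.1% of the sequence weighted by chromosome. Introns held 546 summits (27.2% against 33.7%), coding exons 65 (3.24% against 24.3%), 5' UTRs 58 (2.89% against 1.41%) and 3' UTRs 24 (1.20% against 3.37%), and all 5 classes differed from their share of sequence (exact binomial tests, largest adjusted p = 6.4e-07). Gene starts lay within 1 kb of 850 summits (42.4%, Wilson interval 40.2% to 44.6%) against 33.9% ± 1.07 (SD over random placements), a ratio of 1.25 (permutation p = 0.0001, the smallest that 10000 draws can give). Within 500 bp the ratio was 1.76 and within 2 kb it was 1.06. Random placements fell in coding exons too, and placement within classes of location was not run for gene starts. The ratio is thus not separated from the excess of summits between genes. The share near a gene start was 46.0%, 40.1%, 42.1% and 41.3% in 4 bins of about as many peaks each, from the weakest to the strongest, with no test made. Summits within 200 bp of a tRNA gene numbered 18 (0.898%) against 0.301% at random, a ratio of 2.99 (permutation p = 0.0001, again the smallest possible), and 2.57 with each summit placed within its own class of location, a placement added after the data were seen (permutation p = 0.0002). Summits were treated as independent in these tests, although some share a locus.

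Ribosomal protein, translation factor, respiratory chain and pan-neuronal genes carried peaks more often than other genes. Of 81 ribosomal protein genes, 28 (34.6%, exact interval 24.3% to 46.0%) had a peak against 3.96% of all other protein-coding genes (adjusted p = 1.5e-17), led by rpl-3, rpl-15, rpl-35 and rpl-12. Without replicate 1, 18 of the 81 had a peak (Fisher's exact test, adjusted p = 1.3e-08), and the difference from other genes fell from 30.6 to 18.5 percentage points. Of 38 translation factor genes, 8 had one (21.1%, Fisher's exact test, adjusted p = 0.000831), among them eef-1A.2, iff-2 (signal 110), eef-2 (signal 67.8) and eif-3.C (signal 48.5). Of 52 genes of the mitochondrial respiratory chain, 16 had one (30.8%, Fisher's exact test, adjusted p = 1.5e-09), among them cox-5A (signal 96.9), cox-5B (signal 81.9), atp-1 (signal 50.03) and mev-1 (signal 40.1), which encode subunits of cytochrome c oxidase, ATP synthase and succinate dehydrogenase. Without replicate 2, 10 of the 52 had one (Fisher's exact test, adjusted p = 0.000333), and the difference fell from 26.8 to 15.2 percentage points. The respiratory chain genes were mostly at weaker peaks, since only 3 of the 52 had a peak among the 1002 strongest (Fisher's exact test, adjusted p = 0.275).

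Of 30 pan-neuronal genes, 11 (36.7%, exact interval 19.9% to 56.1%) had a peak (Fisher's exact test, adjusted p = 1.1e-07). The difference from other genes depended on the window, at 20.2 percentage points with 500 bp, 32.6 with 1 kb and 47.9 with 2 kb. The strongest were at unc-104 (chromosome II, 6994713 to 6995076, signal 65.9), which encodes a kinesin of synaptic vesicle transport, syd-2 (signal 65.0), which encodes a liprin of presynaptic assembly, maco-1 (signal 60.9) and rgef-1 (signal 57.7). The marker gene unc-119 was itself 1 of the 11, and without peaks within 20 kb of it the list stayed past the threshold (Fisher's exact test, adjusted p = 1.5e-06).

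Smaller lists passed with few genes. Cell cycle genes had 6 of 38 (15.8%, Fisher's exact test, adjusted p = 0.0232), with lin-9, lin-53, efl-1 and pcn-1 at signals of 64.9, 62.2, 61.1 and 57.5. The first of these encode members of the DREAM and retinoblastoma pathway and pcn-1 encodes PCNA. Heterochronic genes, which time larval stages, had 4 of 20 (Fisher's exact test, adjusted p = 0.0336): ain-1 (signal 65.0), apl-1 (signal 64.9), lin-28 (signal 43.6, in its 5' UTR) and kin-20 (signal 43.0, in its intron). All 4 summits lay over 500 bp from the gene start. Vacuolar ATPase genes had 4 of 21 (19.05%, Fisher's exact test, adjusted p = 0.0357): vha-12, unc-32, vha-15 and vha-13, at signals of 45.2, 43.4, 40.2 and 30.1. By Fisher's exact test on the strongest regions of replicate 2 alone, the cell cycle (adjusted p = 0.0667) and heterochronic (adjusted p = 0.132) lists were no longer past the threshold, and with those of replicate 1 alone the vacuolar ATPase list, at 2 of 21, was not (adjusted p = 0.544). Fisher's exact test also missed the threshold for cell cycle genes with a 2 kb window (adjusted p = 0.0565), and for vacuolar ATPase genes with windows of 500 bp (0.0941) and 2 kb (0.0728) and in the 1002 strongest peaks (0.244). With a 500 bp window the heterochronic genes had fewer peaks than other genes (−3.18 percentage points, Fisher's exact adjusted p = 1). Adjusted p-values of lists are over 34 lists.

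Large families of sensory and degradation genes were nearly free of peaks. Chemoreceptor genes had 7 of 1365 (0.513%, exact interval 0.206% to 1.05%) against 4.34% of other genes (Fisher's exact test, adjusted p = 5.9e-16). The strongest were at sri-5 (signal 59.9), srx-125 (signal 44.5), sru-26 (signal 38.5) and srh-75 (signal 34.7), and the peak at sri-5 lay within 1 kb of the start of rsr-1 too, named after its values were seen. F-box genes had 4 of 322 (1.24%, Fisher's exact test, adjusted p = 0.0303), namely fbxb-58 (signal 130), fbxb-85 (signal 65.9), fbxb-21 (signal 39.6) and fbxb-16 (signal 31.3). The F-box list was not past the threshold with replicate 2 alone (Fisher's exact test, adjusted p = 0.216), with a 500 bp window (0.0642) or in the 1002 strongest peaks (0.244). As at sri-5, the peaks at iff-2, eef-2, atp-1, mev-1, lin-53, efl-1 and fbxb-85 lay within 1 kb of another gene's start too.

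The other 25 lists did not pass the threshold. Peaks were assigned to 5 of 39 splicing factor genes, 3 of 29 Wnt signalling genes, 4 of 41 bHLH factor genes, 3 of 32 aminoacyl-tRNA synthetase genes, 3 of 33 proteasome subunit genes, 2 of 23 heat shock protein genes, 2 of 26 insulin signalling and DAF-16 target genes and 2 of 32 body wall muscle genes. The Wnt signalling gene hmp-2 and the proteasome gene pbs-5 lay in the dense block on chromosome I described last, both named after their values were seen. Of the 15 forkhead family genes, daf-16 and fkh-9 had a peak, both named after their values were seen. Homeobox genes had 5 of 93, nuclear hormone receptors 10 of 274, cilia genes 3 of 61, neuropeptides and insulins 3 of 140, cuticle collagens 2 of 175, histones 2 of 72 and germline genes 2 of 51. TGF-beta, Notch, EGF and Ras signalling and axon guidance had 1 gene each, of 20, 22, 29 and 36. No peak was assigned to the 36 intestine, 31 major sperm protein, 27 molting, 23 pharynx or 17 epidermal transcription factor genes. Without replicate 1, peaks were assigned to 1 aminoacyl-tRNA synthetase, 1 cilia, 1 germline, 0 Notch signalling, 3 axon guidance and 6 neuropeptide and insulin genes. Without replicate 2, they were assigned to 0 insulin signalling and DAF-16 target, 1 forkhead family, 1 histone, 3 homeobox and 5 proteasome subunit genes. Leaving out the 2 blocks of dense summits lowered the difference of Wnt signalling genes from other genes from 6.27 to 2.91 percentage points. For proteasome subunits it fell from 5.02 to 2.07 points. For the lists with no peak, exact intervals reached up to 9.74%, 11.2%, 12.8%, 14.8% and 19.5%. By Fisher's exact test, heat shock protein (adjusted p = 0.000934) and splicing factor genes (0.0149) passed when every gene start within 1 kb was counted, Wnt signalling (0.00386) and axon guidance (0.0115) with a 2 kb window, proteasome subunits with replicate 1 alone (0.0382), and cuticle collagens, with fewer peaks than other genes, with a 500 bp window (0.036).

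**Figure D2:**
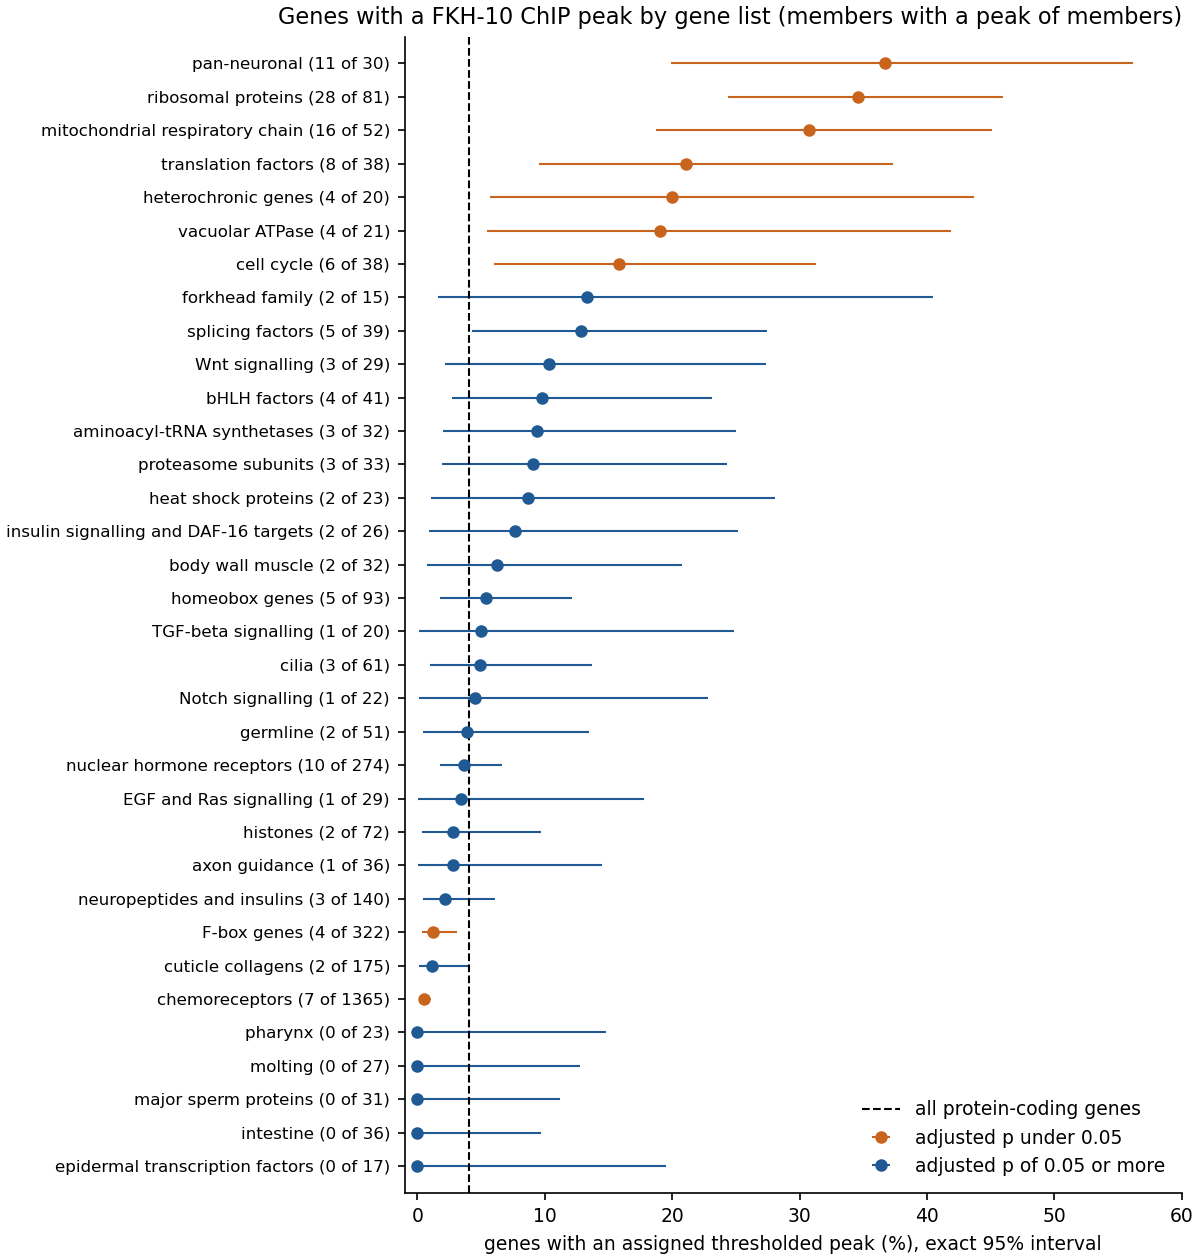
Share of the members of each gene list with an assigned thresholded peak (x axis, percent) with exact 95% intervals, in orange for lists with an adjusted p under 0.05 and in blue for the others, and a dashed line at 4.08% of all protein-coding genes. Pan-neuronal (36.7%), ribosomal protein (34.6%) and respiratory chain genes (30.8%) stand at the top, and chemoreceptors at 0.513% lie below the line.

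The forkhead core RTAAAYA was rarer at summits than beside them, but its form GTAAACA was not. RTAAAYA, the core that forkhead domains are known to bind, was present within 50 bp of 111 summits (5.54%, Wilson interval 4.62% to 6.62%) and in 216 windows 500 bp away (10.8%, interval 9.49% to 12.2%; exact McNemar p = 1.4e-09). The weakest pooled regions carried it at 10.3% of summits. GTAAACA alone was present at 27 summits and in 22 control windows (exact McNemar p = 0.56). The largest drop was in ATAAATA, made only of A and T, at 36 summits and in 117 control windows (exact McNemar test, adjusted p = 1.2e-09). ATAAACA was at 29 and 54 (exact McNemar test, adjusted p = 0.0385) and GTAAATA at 24 and 41 (adjusted p = 0.152). The presence of RTAAAYA had no detectable relation to signal (rho −0.00484, permutation p = 0.828; −0.0408, p = 0.0666 without replicate 1 and −0.0283, p = 0.205 without replicate 2), with 6.37%, 4.79%, 4.39% and 6.59% of peaks in the 4 bins from the weakest to the strongest. The summit windows held 43.5% ± 8.69 G and C (SD over 2005 windows) and the control windows 34.8% ± 8.48. At the summits RTAAAYA was not distinguishable from its bases in other orders, being 2.24 percentage points below their median (p by rank among 210 orders = 0.429).

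Purine-only and pyrimidine-only 7-mers were mostly more frequent at the summits, and those of A and T less frequent. Of 8192 7-mers, 899 (10.97%) were more frequent at summits and 763 (9.31%) less frequent (exact McNemar tests, Benjamini-Hochberg). Among the 10 with the smallest p, 6 were higher at summits. CTCTCTC was present at 11.5% of summits against 1.30% of control windows, AGAGAGA at 11.4% against 1.95%, AAGAAGA at 15.2% against 3.89%, CTTCTTC at 12.7% against 2.89%, GAAGAGA at 10.1% against 1.70% and GAGACGC at 8.63% against 0.948%. The other 4 were lower, with TTAAAAA at 3.99% against 17.9%, TTTAAAA at 3.14% against 14.6%, AAAAATT at 9.08% against 23.6% and ATTTTTA at 3.89% against 15.01%. Adjusted p-values for these 10 were 5.7e-29 or smaller. Of 128 7-mers made only of purines or only of pyrimidines 122 were higher, of 64 made only of A and T 63 were lower, and of 48 containing GACGC 19 were higher and 0 lower. These classes were chosen after the 7-mers were seen. No 7-mer test adjusted for base composition, which was 43.5% G and C in summit windows and 34.8% in control windows. The drop of 7-mers of A and T was thus not separated from it.

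**Figure D3:**
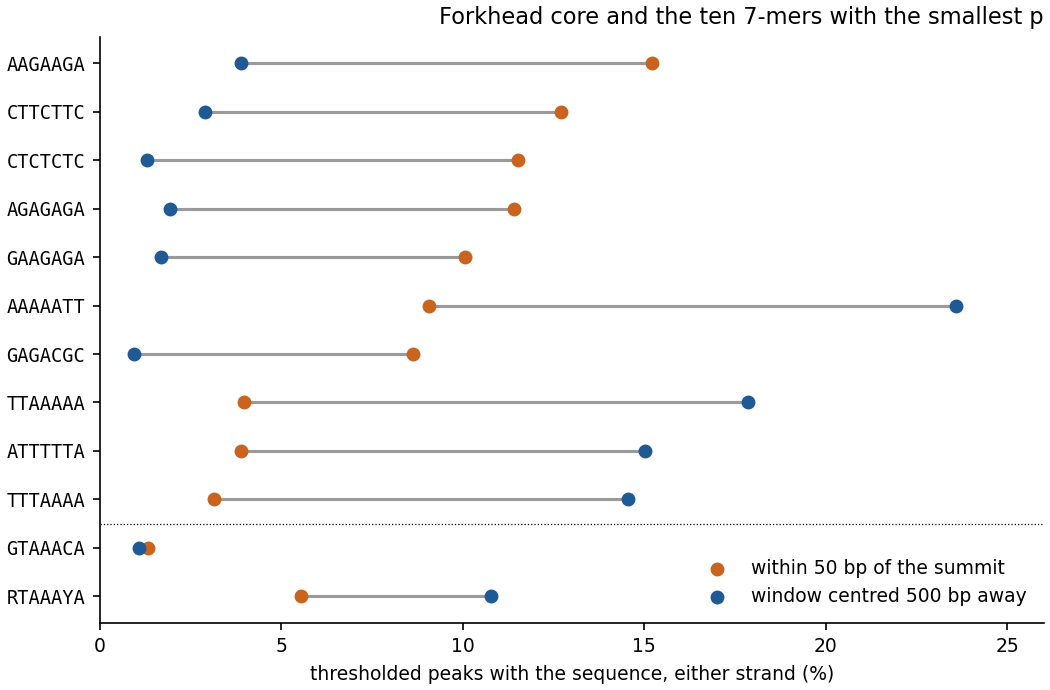
Percent of the 2005 thresholded peaks with each sequence on either strand (x axis), in orange within 50 bp of the summit and in blue in a window centred 500 bp away. Below the dotted line, RTAAAYA is at 5.54% against 10.8% and GTAAACA at 1.35% against 1.10%. Above it are the 10 7-mers with the smallest p.

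The X chromosome held more peaks, and chromosome V fewer, than their shares of genes. X had 459 peaks (22.9%, Wilson interval 21.1% to 24.8%) against 13.7% of protein-coding genes (exact binomial test, adjusted p = 5.8e-28), and V had 303 (15.1%), where its share of genes would give 501 (adjusted p = 1.5e-26). Chromosome I was above its share with 374 peaks (18.7% against 14.4%, exact binomial test, adjusted p = 3.5e-07) and II below with 275 (13.7% against 17.3%, adjusted p = 2.7e-05). Chromosomes III (14.6% against 13.2%, exact binomial test, adjusted p = 0.0836) and IV (15.01% against 16.4%, adjusted p = 0.0914) did not pass. Against chromosome length, X remained above (17.7% of length, exact binomial test, adjusted p = 9.3e-09), II no longer passed (adjusted p = 0.0697), and IV did (adjusted p = 0.00587). Without the 2 blocks of dense summits described next, chromosome I stood at 16.6% (exact binomial test, adjusted p = 0.0106) and III passed at 15.2% (adjusted p = 0.0139).

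**Figure D4:**
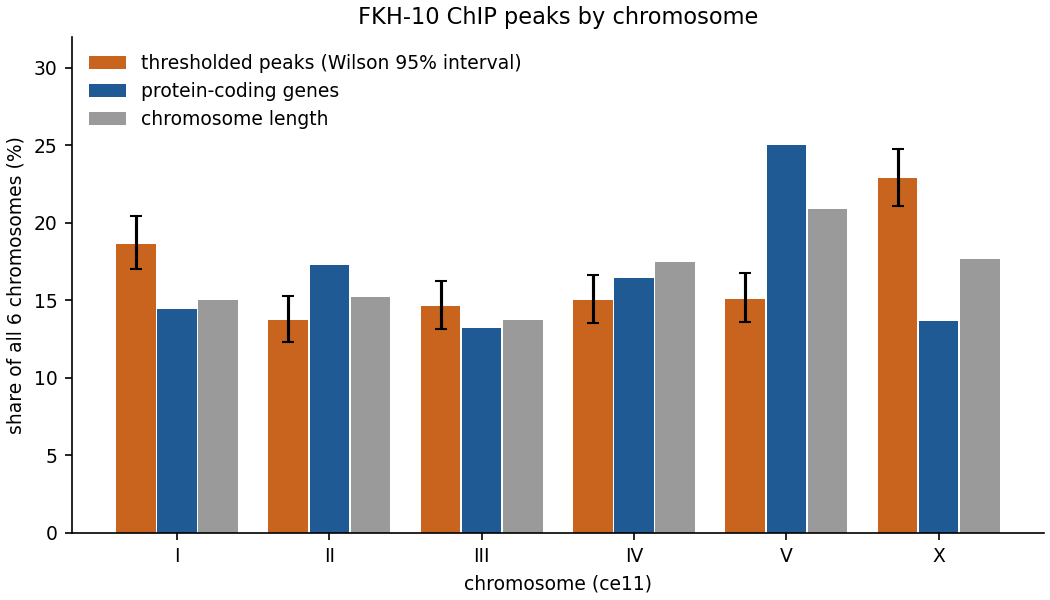
Share of thresholded peaks on each chromosome (orange bars, percent, with Wilson 95% intervals) beside its share of protein-coding genes (blue) and of length (grey). X holds 22.9% of peaks and 13.7% of genes, and V holds 303 peaks against 501 expected from its share of genes.

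Thresholded summits were packed densely in 2 places. On chromosome I, 54 summits lay between 14719505 and 14769125 (49621 bp), with signals of 28.4 to 122, and 57 and 70 of the 2005 strongest regions of replicates 1 and 2 lay there too. On X, 25 summits lay between 16344441 and 16378299 (33859 bp), with signals of 29.1 to 82.0, and 25 and 27 in the replicates. Pooled regions covered 72.2% of the block on I and 57.1% of that on X, against 13.3% and 17.8% of the flanks and 10.6% of the genome. In coding exons lay 18 of the 54 summits on I (33.3%) and 6 of the 25 on X (24.0%), against 2.13% of the peaks outside the blocks. The block on I overlapped 16 protein-coding genes, among them pbs-5 and hmp-2, which encodes a beta-catenin. The block on X overlapped taf-3, nhr-28, which encodes a nuclear hormone receptor, ace-1 and sur-7. These genes and blocks were named after their values were seen.

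**Figure D5:**
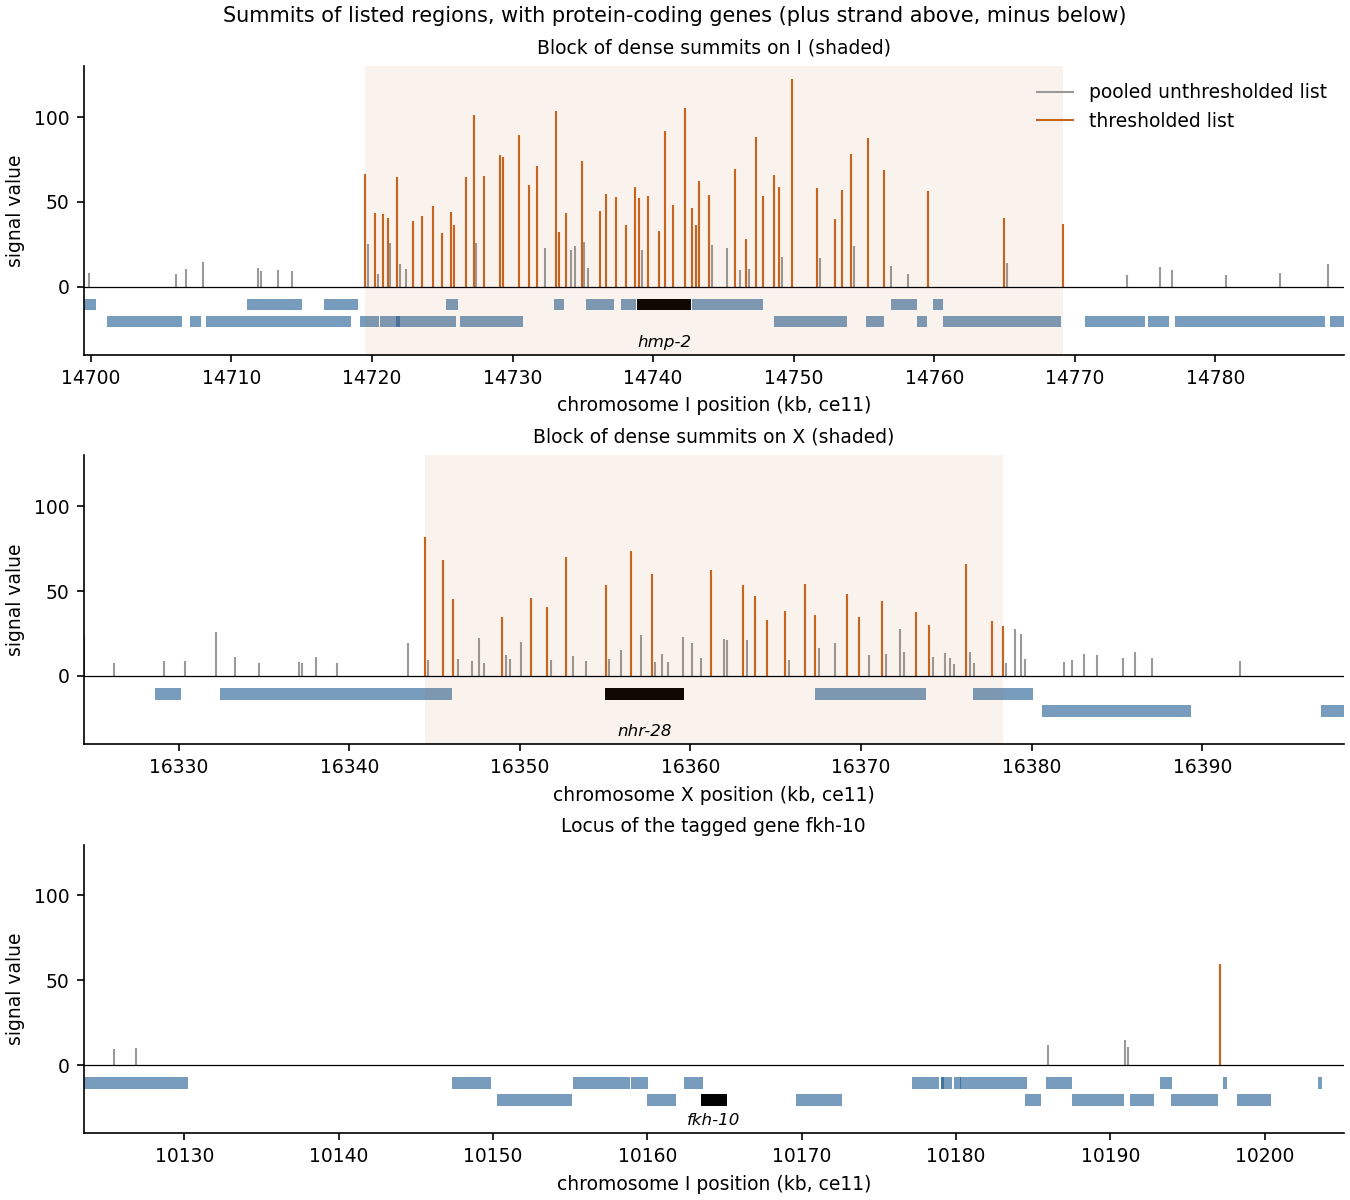
Signal value (y axis) of each summit in the pooled list (grey) and the thresholded list (orange) along the block on chromosome I, the block on X and the fkh-10 locus (x axes in kb, ce11), with protein-coding genes as bars below and hmp-2, nhr-28 and fkh-10 in black. The shaded blocks hold 54 and 25 thresholded summits, and no summit lies within 20 kb of fkh-10.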

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

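The analysis without the 2 blocks of dense summits and the placement within classes of location were chosen only after the data were seen, and the others were planned. Of 56 alternative values of the main results, 48 kept their direction and their side of the threshold or stayed within the limits set for a count or share. The motif result went the other way with GTAAACA only, at 0.249 percentage points above the control windows, and missed the threshold against its bases in another order (−2.24 points). In the other alternatives it lay between −9.18 and −2.54 points, and leaving out a replicate gave −5.44 and −4.64. Spearman's rho of motif and signal, never past the threshold, changed sign to 0.0296 in the 1002 strongest peaks and moved from −0.00484 to −0.0408 without replicate 1 and −0.0283 without replicate 2. The count of 7-mers higher at summits moved from 899 to 446 in the 1002 strongest peaks, where fewer peaks were tested, and to 1350 with a window of 100 bp. The share of peaks covered by both replicates moved from 60.9% to 56.3% with a reciprocal overlap of 50% of each interval, to 54.3% with summits within 100 bp, and to 87.0% with the 4010 strongest regions, which are more regions by construction. The promoter ratio ran from 1.06 to 1.76 and the tRNA ratio from 1.83 to 4.12. The gene lists past the threshold numbered 6 to 11. Alternative values of single lists were counted only for lists past the threshold in at least 1 setting. Of these 135 values, 12 lost and 6 gained their call, and 4 turned, with 1 of the losses and 1 of the gains among them. Turns in lists never past the threshold were not counted. Notch signalling was such a list, 0.465 points above other genes at first and with 0 genes without replicate 1. Axon guidance, not past the threshold at first, turned to 0.746 points in the strongest peaks, 4.53 without replicate 1 (−1.29 without replicate 2) and 13.97 with a 2 kb window (Fisher's exact test, adjusted p = 0.0115), and heterochronic genes turned to −3.18 points with a 500 bp window. Beyond those named above, the cause was not tested. Of 40 ranks of strong peaks in a single replicate, 22 moved. The ce10 signal at fkh-10 was not run, because no ce10 annotation was used here, and leaving out a replicate has no meaning for the overlap of both. No depth per library is known, so its effect on the number of peaks cannot be given.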

Other observations

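The orders of the motif's bases, planned as an alternative, were put to use as a test of an explanation only after the result was seen. The coverage test of the block on I, the coding-exon tests, the count of gene starts at fkh-10, the sequence GCGTGTTTT and the definition of the blocks were also chosen after results were seen. The remaining tests were set before their results were seen.

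Several of the strongest peaks shared a sequence that the 7-mer tests had not singled out. GCGTGTTTT lay within 50 bp of the summits at rpl-3, cdc-48.1 and rpl-35, 3 of the 20 strongest peaks. Over the thresholded list it was present at 9 summits (0.449%) and in 1 control window (exact McNemar p = 0.0215). The sequence was noticed in these windows, so the p is not independent evidence.

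Strong peaks on X away from gene starts may include recruitment sites of the dosage compensation complex, which is loaded on X in hermaphrodites at sites carrying a motif with the core GCGCAGGG. Among the 1002 strongest peaks, those over 1 kb from a gene start had this core within 100 bp of the summit at 9 of 168 on X (5.36%) and at 0 of 416 on autosomes (Fisher's exact p = 1.2e-05), and at 0 of the 168 X windows 500 bp away. Base composition did not account for it, since the 167 other orders of the same bases were present in at most 4 of the X windows, below GCGCAGGG at the 100th percentile. Of the 20 strongest peaks, those in introns of Y41G9A.17 and mom-1 carried the core. Most of the X peaks did not carry it, and no ChIP of the complex was analysed here.

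In the block of dense summits on I, 61.1% of the summits and 51.2% of the bases lay within 1 kb of a gene start (exact binomial p = 0.173), in that on X 4 of 25 summits and 17.7% of the bases (p = 1), and around fkh-10, where no summit lay, gene starts were not few, with 13 within 20 kb (percentile 75.7 of all other protein-coding genes). On I the share of summits near gene starts was above that of the bases without passing the threshold, so it left the question open there. Clustered gene starts alone did not account for the summits in coding exons. Summits that avoided coding exons as peaks elsewhere did, near and far from gene starts, would lie in them at 2.82% on I and 1.21% on X. The observed shares were 33.3% (exact binomial p = 4.7e-15) and 24.0% (p = 4.5e-07). Neighbouring summits of a block are not independent, so exact binomial p-values over them overstate the evidence. More copies of each segment in the ChIP material than in the control would raise coding and other sequence alike. The coding-exon shares were far above that of peaks outside the blocks (exact binomial p = 3.8e-17 and 1.2e-05). Coding bases made up 36.1% on I (exact binomial p = 0.777) and 11.8% on X (p = 0.11), where 25 summits leave a difference open. The coverage of 72.2% on I and 57.1% on X fell short of the 75% set for this explanation. Over the genome, however, 99.7% of pooled regions had 1 fixed width, a share not counted within the blocks, where a wider peak lay on I. Sequence between listed regions was thus not shown to be low. The explanation stays open without the control's coverage, which was not analysed here. Whether the control held more copies of the fkh-10 segment, or a strain differed from its label, was not tested, so that which protein the peaks belong to rests on the labels alone, and the design gave no biological explanation to test.

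The shortage of RTAAAYA at summits is consistent with their base composition, since its ratio of summit to control windows (0.514) stood at percentile 70.3 among the 209 other orders of its bases. GTAAACA, which was not rarer at summits, was not set against its bases in other orders. No other factor's ChIP was analysed here, so binding of FKH-10 without its core and recovery independent of FKH-10 were not separated.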
